A study of Mus musculus with 2 samples.

How the data were processed

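DNase-seq maps DNase I-hypersensitive sites, the stretches of chromatin open enough for the nuclease to cut. It was applied to hindbrain tissue of mouse embryos at embryonic day 14.5, of the B6NCrl strain with both sexes pooled, per the labels. The labels give 1 group with 2 biological replicates, each a separate tissue sample and a separate library. There is no other tissue, stage or treatment, so the replicate comparison is the one comparison the design implies, and everything else describes the sites that both libraries share.

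For each library the authors deposited a list of peaks and a list of hotspots, the wider regions of enriched cutting. Both were derived separately for each replicate from filtered alignments to mm10, per the text deposited with each sample. The aligner, the peak caller, their versions and the thresholds are not given in the sources used here. The deposited peaks are all 150 bp wide and carry a score, a whole number that never passes the peak width. What the score counts, and whether it was scaled for sequencing depth, is not stated, so scores were compared between libraries by rank, with a Pearson correlation of the scores beside the rank correlation. The deposited hotspots carry a −log10 q-value, which runs from 1.30 to 6.00 or equals 100. No hotspot lies between those values, so 100 was taken as a cap for all regions past the finest q the authors could resolve. The files hold no read counts, so the depth of each library is unknown. Confidence intervals of overlap shares are 95% Wilson intervals over peaks. They cover counting error only, not the spread between embryos.

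Coordinates are mm10, and every peak and hotspot end lay within the chromosome lengths of GRCm38, the same assembly. Sequence came from GRCm38.p6 and gene models from the basic set of GENCODE mouse release M21. Peaks on the mitochondrial genome and on unplaced contigs were left out of the comparisons. A peak was shared when at least 1 bp of it overlapped a peak of the other library, and private otherwise. Sets of shared peaks use the positions of replicate 1. The chance level of overlap came from 100 seeded shuffles of a library's peaks within chromosomes, avoiding assembly gaps, with a one-sided p. A promoter peak had its midpoint within 1 kb of an annotated transcription start site (TSS), and a distal peak lay farther than that from every TSS. A gene's distal count is the number of distal peaks within 50 kb of its TSS, so neighbouring genes can count the same peak.

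Before the data were examined, 23 gene lists, 25 consensus motifs, the tests and the alternatives were fixed, and 1134 olfactory receptor genes served as a further list that brain tissue should not use. The 24 lists were set against random lists of the same size, 10000 draws each (2000 for olfactory receptors). For promoters, random genes came from the same of 10 classes of CpG observed/expected ratio within 500 bp of the TSS. For distal counts they also matched in deciles of local TSS density, which ties merged into 6 classes. Permutation p-values are two-sided and were adjusted over the 24 lists by the Benjamini-Hochberg method. These tests describe the 2 libraries and not a population of embryos. Matched random genes are scattered over the genome while Hox genes sit in clusters and share peaks. A further background, chosen after seeing the data, therefore shifted each list along the gene order and kept neighbours together. It did not match CpG content or TSS density. The fixed design held no test of private shares by list. That test was set up after the peak lists had been opened and before any overlap was computed, and its follow-up tests, 80 with peaks and 54 with runs of peaks counted once, came after its result and were not adjusted. Added lists of further forebrain, midbrain and diencephalon, and hindbrain and spinal interneuron genes were written after that result, before their own peaks were examined.

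Motif matches on either strand were counted in 150 bp windows at distal peaks and in as many windows outside all peaks and hotspots, matched in GC bins of 2%. Two-sided Fisher's exact tests were adjusted over the 25 motifs. Each consensus was also set against 5 shuffled versions of itself. Windows are not replicates, so these p-values describe the peak set. Where the background held no match, the ratio was computed against a floor of 3 windows.

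Genes named in the text were chosen by a rule fixed beforehand. It takes, for each list, the 2 members with the most and the 2 with the fewest distal shared peaks, the 10 genes with the most distal shared peaks genome-wide, the genes nearest to the 10 strongest shared peaks and to the 5 longest hotspots of each library, and up to 10 list members whose promoter call differed between libraries. Any member of a list could be named with its value. Names outside that rule are said to be chosen after their values were seen.

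The statistics were tested on simulated data. Planted overlap of 60.0% of 50000 peaks was recovered as 60.0%. With 21911 genes, the distal test called 40% of 10-gene lists raised 2-fold, 90% of those raised 3-fold and 3% of unchanged lists. The promoter test called 95% of 10-gene lists with every promoter closed and 2.5% of unchanged lists. The test of private shares called 100% of 15-gene lists with a raised share and 5.1% of 1000 unchanged lists, a number raised after a first run of fewer unchanged lists had called 8.5%. Alternatives covered the overlap rule, the score threshold, equal numbers of peaks, promoter windows of 500 and 2500 bp, distances of 20 and 100 kb, hotspots in place of peaks, other backgrounds and each replicate alone. All computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.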

Results

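Chromatin accessibility was measured by DNase-seq in the hindbrain of mouse embryos at embryonic day 14.5, the part of the brain that forms the cerebellum, pons and medulla. There was 1 group of 2 biological replicates. After peaks outside the assembled chromosomes were left out, replicate 1 held 263679 peaks and replicate 2 held 148804, a ratio of 1.77. The peaks covered 39.1 Mb in replicate 1 and 21.7 Mb in replicate 2. Hotspots numbered 231347 and 133205 and covered 81.4 Mb and 42.0 Mb. The median peak score was 47 in replicate 1, with quartiles of 35 and 70, and 30 in replicate 2, with quartiles of 21 and 48. Read depth was unknown, so the counts of peaks cannot be set against the amount of sequencing.

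The strongest sites shared by both libraries were promoters. The 10 shared peaks with the highest mean score rank all lay within 1 kb of a TSS, those of Fam76a, Cfap20, Hjurp, Fam76b, Phf12, Ccdc96, Ypel5, Cstf3, Uvrag and Mpp5. The peak at Fam76a (chromosome 4, 132922636 to 132922785, mm10), 153 bp from its TSS, scored 150 in replicate 1 and 133 in replicate 2. The peak at Cfap20, a gene of the ciliary axoneme (chromosome 8, 95434856 to 95435005), also scored 150 and 133. The longest hotspots lay over genes that pattern the brain as well as at other loci. In replicate 1 the longest spanned 8052 bp over Zic2 (chromosome 14, 122472080 to 122480131), and in replicate 2 it spanned 7289 bp at Hoxa2. The next in replicate 1 lay at Tnrc18 (7733 bp), at a non-coding start site 46714 bp from Rhbg (6563 bp), at Mex3b (6545 bp) and at Pcdh7 (6449 bp). Those in replicate 2 lay at Zic4 (6632 bp), Tnrc18 (6166 bp), Marcks (5728 bp) and Myc (5225 bp). Hotspots of the other replicate covered between 43.6% of the length, at Zic2, and 100%, at Tnrc18 in replicate 2.

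The replicates shared most of their strong sites and differed mainly in their weak ones. Of the replicate 2 peaks, 114674 of 148804 overlapped a replicate 1 peak (77.1%, Wilson interval 76.8% to 77.3%), against a mean of 3.16% for shuffled peaks. Of the replicate 1 peaks, 111722 of 263679 overlapped a replicate 2 peak (42.4%, 42.2% to 42.6%), against 1.79% for shuffled peaks. In both directions the permutation p was 0.0099, the smallest that 100 shuffles can give. In the highest score decile of replicate 1 97.3% of peaks were shared, and in the lowest 6.42%. The corresponding shares in replicate 2 were 99.2% and 18.0%. Across the 111722 shared peaks, which are not independent replicates, the Spearman correlation of scores was 0.857 and the Pearson correlation 0.879. The median distance between paired midpoints was 20 bp. Hotspots overlapped in 41.6% of replicate 1 and 84.8% of replicate 2 cases. Those at the q-value cap did so in 85.0% and 95.9%.

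**Figure D1:**
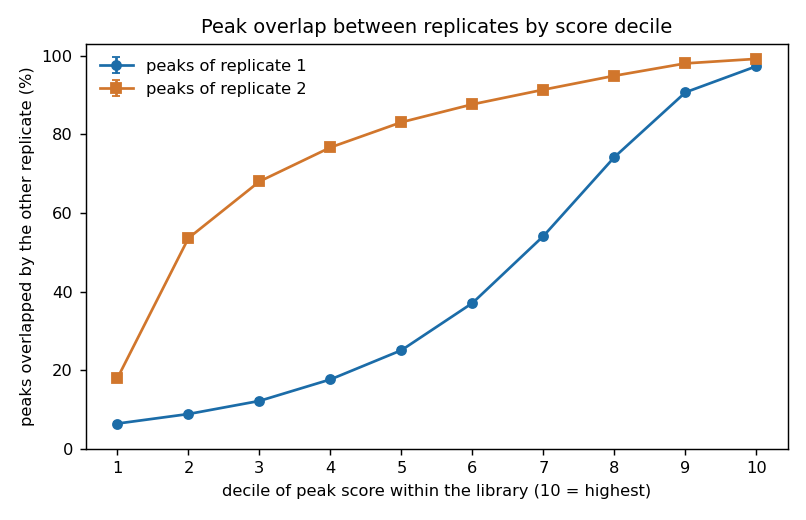
Percent of each library's peaks that overlapped a peak of the other library, by decile of the score within the library, with 95% Wilson intervals that are smaller than most symbols. The share went from 6.42% in the lowest to 97.3% in the highest decile of replicate 1, and from 18.0% to 99.2% in replicate 2.

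Promoters made up a large part of the shared sites. Of the 111722 shared peaks, 27.5% lay within 1 kb of a TSS, 3.75% in exons, 35.3% in introns and 33.5% between genes. Shuffled peaks fell at promoters in 4.50% of cases, so the share was 6.10 times the chance level, and no shuffle passed 4.62%. Replicate 1 had 17.4% of its peaks at promoters and replicate 2 had 26.7%. Of 21911 protein-coding genes, 14268 (65.1%) had a shared promoter peak. The share was 6.75% in the lowest and 98.4% in the highest of 10 classes of promoter CpG content. The promoter call was the same for most genes, with 14359 called in both libraries, 6344 in neither, 1067 in replicate 1 alone and 141 in replicate 2 alone.

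Promoters of neuronal genes and of anterior Hox genes were accessible, and those of posterior Hox genes were mostly not. All 16 genes of the pan-neuronal list, among them Tubb3, Dcx, Stmn2, Map2, Rbfox3 and Snap25, had a shared promoter peak, against 10.9 for CpG-matched genes (adjusted permutation p = 0.00192). Hox genes set position along the body axis, and the hindbrain uses the low-numbered paralogues. Of the 15 Hox genes of paralogue groups 1 to 5, 12 had a shared promoter peak, and Hoxb1 and Hoxd4 were among those without. Random lists held 12.3, and the adjusted permutation p was 1. CpG matching and distal counts used the outermost annotated start of a gene, which for some Hox genes lies near another Hox gene. That of Hoxc5 (chromosome 15, 102967443) lay near that of Hoxc10 (102966796), and both genes were called. That of Hoxa3, which was not called, lay between those of Hoxa6 and Hoxa7 (chromosome 6, 52213336). Only Hoxa7 of the 8 genes of groups 6 to 8 had one, against 6.93 for matched genes (adjusted permutation p = 0.0016). Of the 16 genes of groups 9 to 13, only Hoxa10 and Hoxc10 did, against 14.9 for matched genes (adjusted permutation p = 0.0016). With shifts along the genome that keep the Hox clusters together, the adjusted permutation p was 0.0444 for groups 6 to 8 and 0.0144 for groups 9 to 13. Replicate 1 alone had 6 of the 8 and 9 of the 16, and for groups 6 to 8 the difference from matched genes then no longer passed the threshold (adjusted permutation p = 0.522).

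Among the lists of other hindbrain cells, none passed the threshold above its matched genes and 2 passed below. In the rhombic lip and granule cell lineage, the source of cerebellar granule neurons, 13 of 14 promoters were accessible, among them Atoh1, Barhl1, Zic1 and Zic2, against 12.4 for matched genes (adjusted permutation p = 1). In the cerebellar GABAergic lineage 14 of 15 were, all but the Purkinje cell gene Pcp2, against 12.4 (adjusted permutation p = 0.37). All 15 neural progenitor genes, including Sox2, Nes, Hes5 and Notch1, had a shared promoter peak, against 12.8 (adjusted permutation p = 0.136), and this list passed above with shifts along the genome (adjusted permutation p = 0.0114). Genes of the midbrain-hindbrain boundary had 6 of 10, with Pax5, Pax8, Fgf8 and Wnt1 uncalled, against 8.96 (adjusted permutation p = 0.0096). Brainstem neuron genes had 10 of 17, with Isl1, Lbx1 and Slc17a6 accessible and Phox2a, Gata2, Gata3, Chat and Dbh not, against 14.0 (adjusted permutation p = 0.0258). Replicate 1 alone had 9 of the 10 boundary promoters and 15 of the 17 brainstem promoters, and both lists then had an adjusted permutation p of 1. Both differences were also lost with shifts along the genome (adjusted permutation p = 0.953 and 0.812), with no CpG matching, with a 2500 bp window and with shared hotspots.

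In the main test no further list passed the threshold above its matched genes, and the liver, germ line, forebrain and olfactory receptor lists passed below. No promoter of 12 liver genes, such as Alb, Afp and Apoa1, had a shared peak, against 3.81 expected (adjusted permutation p = 0.0437). In the germ line list only Dazl of 10 genes did, against 7.29 (adjusted permutation p = 0.0016). Of 16 forebrain genes 7 did, including Emx1, Emx2 and Tbr1, against 13 (adjusted permutation p = 0.00192). Only 15 of 1134 olfactory receptor genes had one, against 144 (adjusted permutation p = 0.004). Replicate 1 alone had 87, against 225, and replicate 2 alone had 36, against 163, and both counts still passed below. The remaining lists did not pass the threshold. These were oligodendrocyte lineage (5 of 12), astrocytes (9 of 10), choroid plexus (5 of 9), microglia and blood leukocytes (2 of 12), endothelium (6 of 12), erythroid cells (1 of 10), meninges and mesenchyme (9 of 12), skeletal muscle (5 of 10), epidermis (1 of 10), cell cycle (12 of 12) and housekeeping (14 of 14). With no CpG matching, cell cycle (adjusted permutation p = 0.0216) and housekeeping genes (0.0144) passed above, as did neural progenitors (0.0066), and microglia (0.00617), erythroid cells (0.0056) and epidermis (0.0048) passed below. Astrocytes passed above in 3 alternatives, meninges and mesenchyme above in replicate 1 alone (0.0432), endothelium below among the stronger peaks (0.0126) and skeletal muscle below with a 500 bp window (0.036). The liver difference lost the threshold under 5 of the alternatives, and the forebrain difference did so in replicate 1 alone, where 11 of the 16 promoters were called (adjusted permutation p = 0.112), with no CpG matching (0.203) and with shifts along the genome (0.262).

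**Figure D2:**
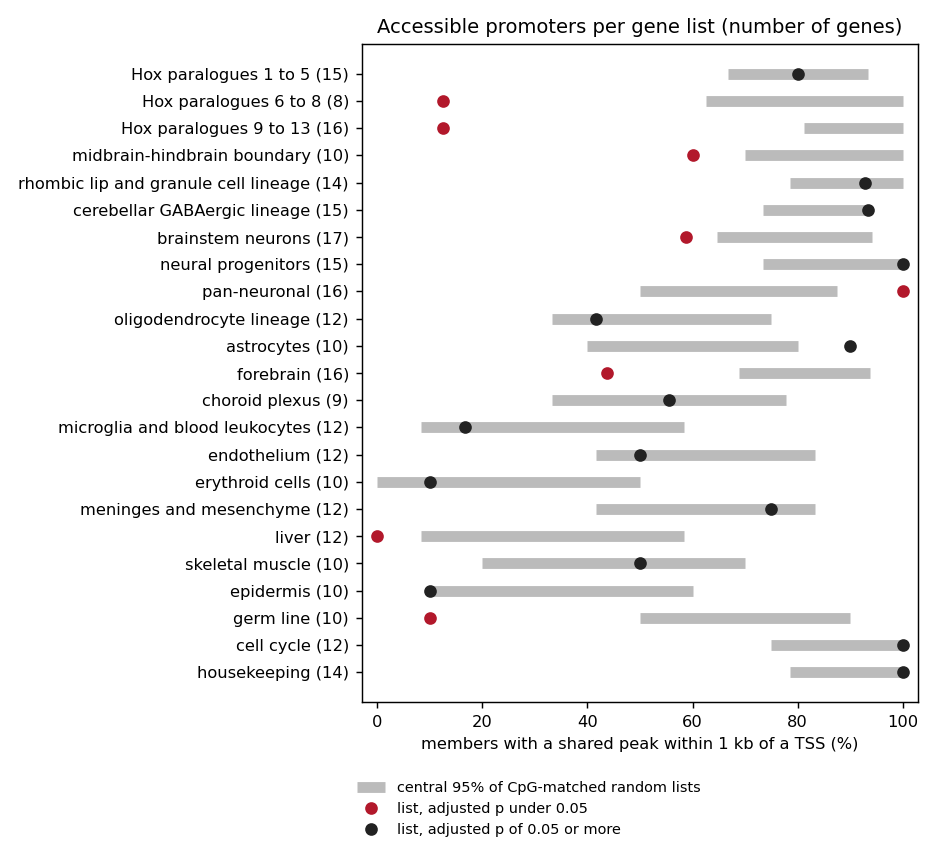
Percent of the genes of each list with a shared peak within 1 kb of a TSS (points) and the central 95% of random lists matched on promoter CpG content (grey bars), over both replicates. The pan-neuronal list lay above its bar at 16 of 16 genes, and the lists of Hox groups 6 to 8 and 9 to 13 lay below theirs at 1 of 8 and 2 of 16.

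Distal sites were dense around genes of the cerebellar GABAergic lineage, pan-neuronal genes and neural progenitor genes. A protein-coding gene had a median of 3 distal shared peaks within 50 kb. The cerebellar GABAergic lineage had a median of 9, against 3.55 for matched lists (adjusted permutation p = 0.0048). Its genes with the most were Slc32a1 with 16 and Gad1 with 15, which encode the vesicular transporter and a synthesising enzyme of GABA, and Calb1 and Pcp2 had 1 each. The pan-neuronal list had a median of 8, against 3.30 (adjusted permutation p = 0.0048), led by Rbfox3 with 18 and Ina with 16. Neural progenitor genes had a median of 8, against 3.52 (adjusted permutation p = 0.0108), led by Notch1 with 19 and Sox2 with 17. Boundary genes had a median of 8, against 3.81 (adjusted permutation p = 0.0256), with 10 at Gbx2 and 9 at En1, a call lost with 50% overlap (adjusted permutation p = 0.1), at 100 kb and in replicate 1 alone (0.0811). At 100 kb the pan-neuronal call (adjusted permutation p = 0.19) and the progenitor call (0.0544) were lost too. Hox groups 1 to 5 also had a median of 8, against 4.23 (adjusted permutation p = 0.024), but the call was lost under 5 of 9 alternatives, among them shifts along the genome (adjusted permutation p = 0.0942) and assignment to the nearest TSS (0.636). The rhombic lip list had a median of 6.5, against 3.58 (adjusted permutation p = 0.0932), although Zic2 had 25, Zic1 21 and Atoh1 15. That list passed the threshold under 7 of its 9 alternatives, each replicate alone included. Brainstem neuron genes, with a median of 5 against 3.65, did not stand apart (adjusted permutation p = 0.522), though in replicate 1 alone they did, with 15 against 8.89 (adjusted permutation p = 0.016).

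The lists of other tissues and of posterior Hox genes did not stand apart in distal counts. Medians were 4.5 for Hox groups 6 to 8, 4 for groups 9 to 13, 4 for forebrain, 5 for liver, 6 for skeletal muscle, 2.5 for epidermis, 3 for germ line and 2.5 for erythroid cells. Oligodendrocyte lineage had 6, astrocytes 5.5, choroid plexus 5, microglia and blood leukocytes 5, endothelium 6, meninges and mesenchyme 3, cell cycle 6.5 and housekeeping genes 6. None of these passed the threshold, though Hox groups 6 to 8 did in replicate 1 alone (14.5 against 7.94, adjusted permutation p = 0.0213) and the oligodendrocyte lineage did at 100 kb (17 against 6.45, adjusted permutation p = 0.0048). Olfactory receptor genes had a median of 0, against 1 (adjusted permutation p = 0.008), a call lost at 20 kb, with the nearest TSS and among the stronger peaks, where matched medians were near 0 too. The liver gene Tat had 13, although its promoter had no peak in either library. Genome-wide the most distal shared peaks lay near Uncx with 43, Adamts18 and Bahcc1 with 37 each, Btn1a1 with 36, Gm49450 and Tuba1a with 33 each, Abt1 with 32, Gm21887 and Klrb1c with 30 each and Ddit4 with 28.

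**Figure D3:**
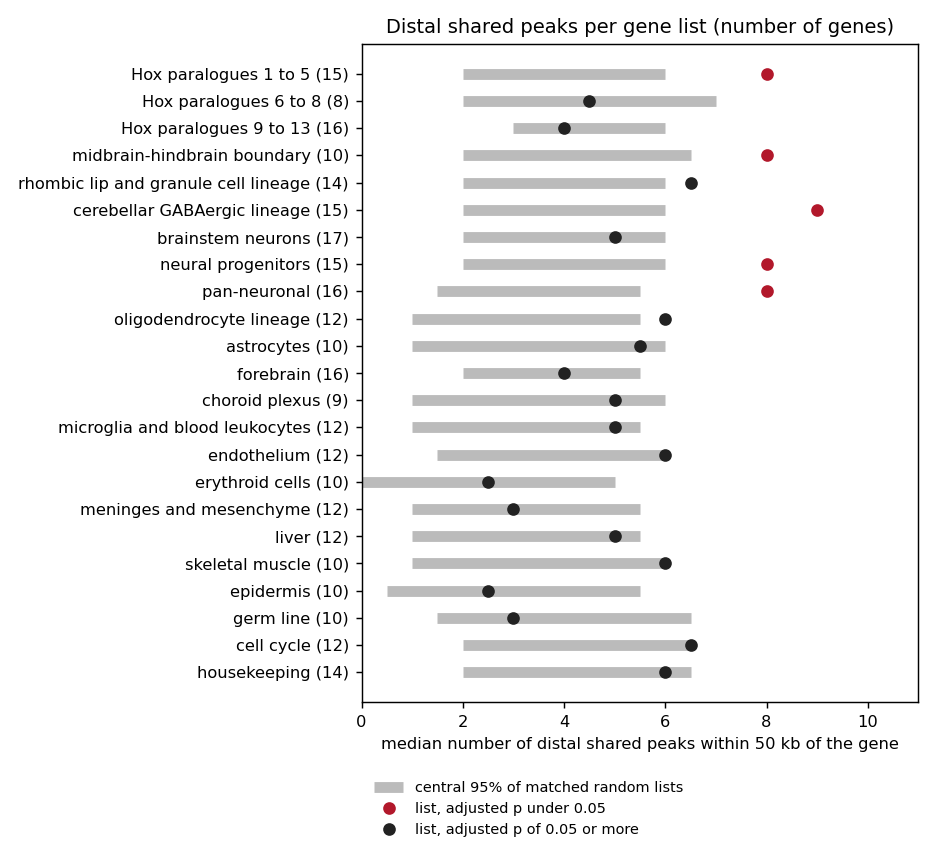
Median number of distal shared peaks within 50 kb of the genes of each list (points) and the central 95% of matched random lists (grey bars). The cerebellar GABAergic lineage had the highest median, 9, and the pan-neuronal, neural progenitor, boundary and Hox 1 to 5 lists had 8.

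Single distal sites were strong in both libraries. A site 5259 bp downstream of the Gad1 start, in an intron (chromosome 2, 70558256 to 70558405), scored 112 in replicate 1 and 88 in replicate 2. An intergenic site 10019 bp past the Zic1 start (chromosome 9, 91355716 to 91355865) scored 132 and 82. A site 15692 bp into Notch1 (chromosome 2, 26500896 to 26501045), also in an intron, scored 128 and 62. Near Gbx2, which is needed for the anterior hindbrain, an intergenic site (chromosome 1, 89943336 to 89943485) scored 109 and 82.

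Distal shared sites were rich in the CTCF, NFI, RFX and REST consensus sequences. The consensus of CTCF, which anchors chromatin loops, was found in 9.33% of 80882 windows, against 0.24% of GC-matched windows (log2 ratio 5.28, standard error 0.10). The NFI consensus was found in 3.34% against 0.276% (log2 ratio 3.60, standard error 0.10). RFX, whose factors act in ciliated cells, matched in 698 windows and 1 background window, a ratio of 698 with an exact interval of 125 to 27609. REST, the site of a repressor of neuronal genes, matched in 169 windows and in no background window, so it was at least 56.3-fold higher. The homeodomain core TAATTA was found in 6.86% against 1.88% (log2 ratio 1.87, standard error 0.04), the POU octamer in 2.95% against 1.02% (1.54, standard error 0.06) and HOX-PBX sites in 1.75% against 0.635% (1.46, standard error 0.07). The E-box CAGCTG was found in 16.6% against 8.44% (0.98, standard error 0.02). NRF1 stood at a log2 ratio of 3.65, SP and KLF sites at 0.91, TEAD at 0.32 and MEF2 at 0.42. MEF2 turned to −0.89 against flanking windows 1 kb away, but stood at 0.74 with GC and repeats matched. The flanking windows were not matched on either. Their median GC content was 44.7%, against 50% in the distal shared windows, and their mean repeat content 25.6%, against 8.43%. By Fisher's exact test 19 of 25 motifs were enriched and 4 were depleted, GATA (−0.42), PU.1 (−0.38), YY1 (−1.26) and HNF4 (−0.35). RUNX did not differ (adjusted exact p = 0.541) and HNF1 had 2 matches (adjusted exact p = 0.521). Only 12 of the 19 lay beyond all their shuffled versions, and the proneural E-box CAGATG (0.48), SOX (0.58), MEIS (0.39), ZIC (0.88), AP-1 (0.19), ETS (0.70) and EBF (1.19) did not, nor did PU.1 among the depleted. Against a background that also matched repeats, the depletion of YY1 (adjusted exact p = 0.234) and the enrichment of TEAD (0.932) and AP-1 (0.81) were lost. Against the unmatched flanking windows YY1 (adjusted exact p = 0.28), TEAD (0.103) and HNF4 (0.158) were lost, and RUNX passed as depleted at −0.26.

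**Figure D4:**
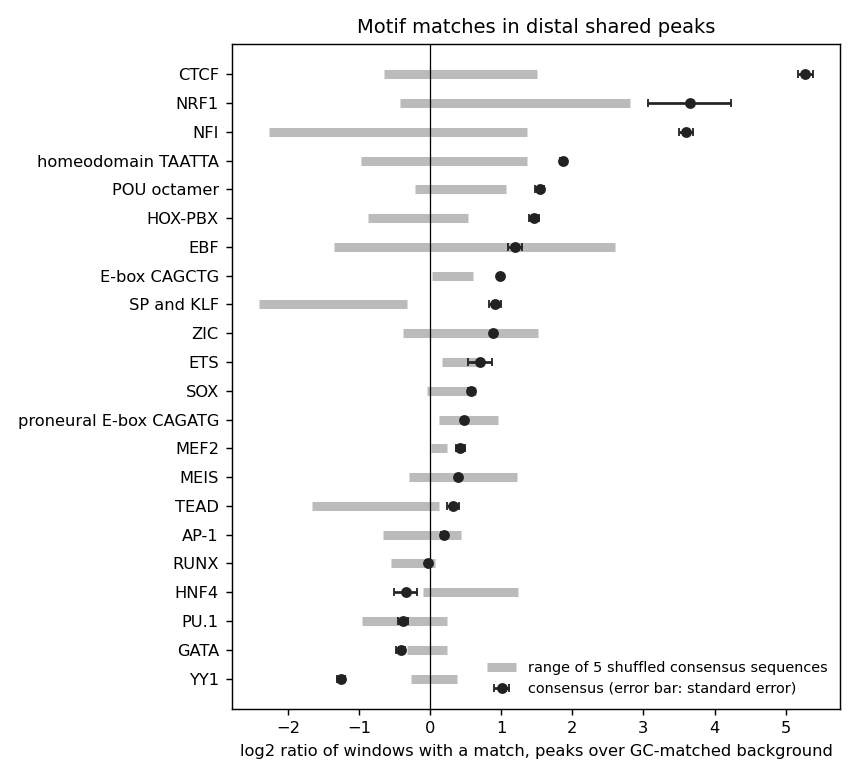
Log2 ratio of distal shared windows to GC-matched background windows with a match to each consensus (points, with standard errors), and the range over 5 shuffled versions of the consensus (grey bars), for the motifs with more than 3 background matches. CTCF stood at 5.28, NFI at 3.60 and the homeodomain core at 1.87, and YY1 stood lowest at −1.26.

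Peaks private to a replicate were weaker than shared ones and were not spread evenly over the gene lists. In replicate 1, 151957 peaks were private (57.6%), with a median score of 38 against 73 for shared peaks and 10% at promoters. In replicate 2, 34130 were private (22.9%), with a median score of 18 against 35 and 24.8% at promoters. Near the forebrain genes 92 of 161 distal peaks of replicate 2 were private (57.1%), against 22.4% for matched lists (adjusted permutation p = 0.0096). The excess was uneven over the members. Emx2, a regulator of cortical patterning, had 23 distal peaks in replicate 2 and 10 in replicate 1, and Dlx5 and Dlx6 had 10 each in replicate 2 and 3 and 4 in replicate 1. Other members went the other way, with 2 and 11 at Six3 and 7 and 15 at Rax. In a further list of 20 forebrain genes, chosen after the first was seen, the private share was 28.8%, against 22.8% (unadjusted permutation p = 0.318). No distal peak of replicate 2 near 10 epidermis genes was private, of 25 (adjusted permutation p = 0.0096), and the share near olfactory receptor genes was 33.1%, against 25% (adjusted permutation p = 0.0096).

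In replicate 1 the private share was high near Hox genes. It was 66.1% near groups 1 to 5, against 46.6% for matched lists (adjusted permutation p = 0.0072), 64.9% near groups 6 to 8, against 44.6% (adjusted permutation p = 0.0348), and 66% near groups 9 to 13, against 45.2% (adjusted permutation p = 0.0048). With shifts along the genome, which keep clusters together but drop the matching, none of these calls remained. The adjusted permutation p was 0.49 for groups 1 to 5 and 9 to 13 and 0.69 for groups 6 to 8. The expected share with shifts was 53.9% for groups 1 to 5 and 9 to 13 and 54.1% for groups 6 to 8. Follow-up settings were set against matched lists only. Among the higher-scoring 50% of replicate 1 peaks the shares were 61.1%, 60.9% and 50.4%, against 21.6%, 20.1% and 21.1% (unadjusted permutation p = 0.0002 for each). With runs of peaks within 1 kb counted once, groups 1 to 5 passed (56.0% against 41.2%, unadjusted permutation p = 0.0062). Groups 6 to 8 (0.0704) and 9 to 13 (0.166) then did not. The share near olfactory receptor genes was 58.0%, against 51.4% (adjusted permutation p = 0.008), and this too was lost with shifts (adjusted permutation p = 0.072). Of 286 list genes, 50 differed in their promoter call, 47 called in replicate 1 alone and 3 in replicate 2 alone. The former included Hoxb1, Hoxd4, Hoxa6, Hoxb6, Hoxb7, Hoxb8, Hoxc8, Hoxa13, Hoxb9 and Hoxb13. With 1 library on each side, these differences describe the pair of libraries.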

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

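The peak lists held sites outside the assembled chromosomes, which no comparison used. On the mitochondrial genome, replicate 1 had 28 peaks and replicate 2 had 32. On unplaced contigs, replicate 1 had 225 peaks and replicate 2 had 271. What singled them out is signal in data outside the main measurement, above the 3 counts that a count of 0 allows. No explanation was tested for them.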

How the results depend on the processing

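The circular shifts, the repeat-matched background and the follow-up alternatives for private shares near gene lists were chosen after the data were seen. Of 84 alternatives for the main values and counts, 48 stayed within the limits set for each and 36 moved. The cause was not tested, except that stricter thresholds, equal numbers and wider windows change by construction what is counted.

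The percent of replicate 1 peaks overlapped was 38.2 with 50% of both peaks required, 51.8 with the higher-scoring 50% of peaks and 65.7 with equal numbers of peaks. For replicate 2 it was 68.5, 92.0 and 67.5. The Jaccard index of covered bases, 0.286, became 0.391 with the higher-scoring 50% and 0.378 with equal numbers, and was not computed for the 50% rule. Hotspot overlap was 27.7% and 48.1% with 50% of both hotspots, and 45.3% and 93.9% for hotspots of at least 500 bp, in replicates 1 and 2. The private share was 61.8% and 31.5% with the 50% rule, and 34.3% and 32.5% with equal numbers. The share of shared peaks at promoters was 36.0% in the higher-scoring 50%, 20.4% with a 500 bp window, 35.5% with a 2500 bp window and between 17.4% and 26.7% in a replicate alone. Genes with an accessible promoter were 62.0% in the higher-scoring 50%, 68.2% with 2500 bp and between 66.2% and 70.4% in a replicate alone.

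Lists with more accessible promoters than matched genes, 1 in the main test, numbered 2 with a 500 bp window, 2 with 2500 bp, 4 with no CpG matching, 4 with circular shifts and between 1 and 3 in a replicate alone. Lists with fewer, 8, numbered 5 with 2500 bp, 5 with shared hotspots and between 4 and 8 in a replicate alone. For distal peaks, lists above matched genes, 5, numbered 3 at 100 kb and between 6 and 7 in a replicate alone. Lists below, 1, numbered 0 with the higher-scoring 50%, 0 at 20 kb and 0 with peaks given to the nearest TSS. Enriched motifs, 19, numbered 12 against shuffled consensus sequences and 19 in either replicate alone. Depleted motifs, 4, numbered between 3 and 5 in a replicate alone. The MEF2 enrichment of 0.42 reversed to −0.89 against flanking windows 1 kb away, which were not matched in GC content or repeats.

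For single lists and motifs, 546 of 633 alternatives kept direction and side of the threshold, 55 lost the threshold and 31 gained it. Unknown read depth limits what the difference in peak number can show.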

Other observations

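The genes, lists and tests in this part were chosen after the values of the report were seen, except for the tests of replicate 2's sensitivity, of cell makeup and of CpG-rich promoters, whose predictions were written beforehand. Follow-up p-values were not adjusted over the 80 and 54 tests run. Genome-wide, the most distal peaks private to replicate 2 lay near Nr2f1, a regulator of brain patterning, with 46. Tmprss11c had 45, and Cdkn2c and Faf1 had 44 each. The most private to replicate 1 lay near Cxxc5, Mab21l1 and Nr2f2 with 35 each, Rhbg with 32, Pax3 with 31, Flrt1 and Lhx1 with 30 each and Lbx1 with 29. At Tmprss11c 45 peaks spanned 22260 bp with a median score of 5, and at Lhx1 30 peaks spanned 73600 bp with a median score of 44.5.

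Further gene lists were set against the private peaks of replicate 2. Genes of the midbrain and diencephalon had 75 of 143 distal peaks private (52.4%), against 22.5% for matched lists (permutation p = 0.013), but with runs of peaks within 1 kb counted once the share, 24.3% against 13.5%, did not pass the threshold (permutation p = 0.0854). Genes of hindbrain and spinal interneuron classes had 65 of 186 (34.9%), against 22.7% (permutation p = 0.139). A further forebrain list had 46 of 160 (28.8%), against 22.8% (permutation p = 0.318), and all of its 20 genes had more distal peaks in replicate 1.

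Replicate 1 had 1.77 times as many peaks as replicate 2, and lower sensitivity in replicate 2 would leave nearly all of its peaks inside replicate 1's list. The 77.1% found there met the bound set against it, but that bound counted peaks inside replicate 1 hotspots as missing, and with hotspots the share was 85.9%, so this stays open. A different cell makeup of the samples could add sites near genes of other regions, and the share private to replicate 1 near Hox groups 9 to 13 passed the threshold against matched lists (adjusted permutation p = 0.0048), which met the prediction as written. Matched lists treat clustered genes as independent, and with shifts that keep the cluster together, added later, it did not pass (adjusted permutation p = 0.49). The shifts also drop the matching on CpG content and TSS density, and the expected share was 53.9% with shifts against 45.2% with matched lists. Makeup therefore cannot be told apart from clustering or from the change of background. No biological explanation beyond the makeup of the samples was tested, since the design names no second group.

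Some promoters of genes of other tissues were accessible, among them Myod1, Krt10 and Dazl. CpG-rich promoters could give this in any tissue. The prediction was a count level with CpG-matched genes in all 4 lists. Of these, liver, skeletal muscle, epidermis and germ line, 0 had more accessible promoters than CpG-matched genes and 2 had fewer, liver and germ line. The prediction was therefore not met, and no list lay above, so the test cannot decide whether CpG content accounts for the accessible ones. Their CpG observed/expected ratio was 0.841 at Mylpf, 0.734 at Dazl, 0.480 at Myod1, 0.370 at Actn3, 0.346 at Krt10, 0.245 at Ckm and 0.214 at Myh3. Of all genes, 78.0% were called in the CpG class with a median ratio of 0.478, and 26.2% in the class at 0.218. The accessible promoters thus spanned ratios at which most genes were called and ratios at which fewer were. With a 500 bp window 1 skeletal muscle promoter was called, against 5 with 1 kb. Matching on CpG content overstated the count in liver and germ line, and what closes those promoters was not tested.

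Forebrain genes were rich in distal peaks private to replicate 2, unevenly over the members, and 7 of the 16 had more distal peaks in replicate 2. With runs of peaks within 1 kb counted once the share was 34.2%, against 13.7% (permutation p = 0.0016), which argues against dense runs as the whole cause. A forebrain library under a wrong label is argued against by the 12 of 15 promoters of Hox groups 1 to 5 that were accessible in replicate 2. Weak peaks near the calling threshold were not excluded, and forebrain cells or DNA in the replicate 2 sample may be the source, as a hypothesis, but the further forebrain list, at 28.8% against 22.8%, did not pass the threshold (permutation p = 0.318). Its higher-scoring 50% of peaks passed in replicate 2 (14.4% against 4.16%, permutation p = 0.015) and in replicate 1 (43.2% against 28.4%, permutation p = 0.0114), which does not single out replicate 2.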
